A study of Mus musculus with 6 samples.

How the data were processed

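The series describes 6 libraries, a gene expression, a B cell V(D)J and a T cell V(D)J library for each of 2 mice. The 4 V(D)J libraries were analysed. The gene expression libraries were not analysed here, so cell types rest on receptor calls alone. The submitters' processing notes name Cell Ranger 3.0.2 and the mm10 build, without saying which step used each. Each deposited table lists assembled contigs with read and UMI counts, as raw whole numbers that were not normalized, per the file headers, together with a cell call, a confidence flag, V, D, J and constant gene names and the CDR3. The deposited contig lengths and annotations were used as given. How the cell calls and the confidence flag were set is not given in the sources used here. Among contigs with the flag, no further heavy, alpha or beta chain of a cell had under 20% of the first one's UMIs, whereas without the flag 52 WT and 30 564Igi heavy chains did. Gene coordinates come from a RefSeq gene table of GRCm38.p6, the assembly behind mm10.

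A B cell was a barcode called a cell in the B cell table and not in the T cell table of the same mouse, and a T cell the converse. The 345 WT and 373 564Igi barcodes called in both tables are possible doublets and were left out. No doublet caller was run, so doublets within a cell type remain. Their number was estimated from the barcodes called in both tables, assuming that B and T cells share droplets at random, and the second chains they would show from the share of cell pairs with different chains, with intervals from 1000 draws of both counts. Contigs had to be high-confidence, productive and supported by at least 2 UMIs. The primary heavy, light, alpha or beta chain of a cell was the contig with most UMIs. The candidate knock-in chains were the heavy and kappa CDR3 nucleotide sequences that were primary in most 564Igi B cells. A second chain was a further productive chain with another CDR3. Net charge counted arginine and lysine minus aspartate and glutamate. A clonotype shared V gene, J gene and CDR3 nucleotides of both chains. Expansion was measured after drawing both mice to the same number of cells, as the mean of 1000 draws with their central 95%. Gene usage profiles were compared by total variation distance, with the counting noise taken from 1000 draws of both mice from their pooled profile.

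Shares carry exact (Clopper-Pearson) 95% intervals and differences, always 564Igi minus WT in percentage points, Newcombe intervals built from them. A count of 0 is given with the share that 3 counts would make. With 1 mouse per group there is no test between groups, and no p-value was computed. Samples, measures, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes had at least 20 cells in either mouse and exact intervals that did not overlap, up to 5 higher and 5 lower per V locus and 3 per J locus, with all isotypes, the members of 10 gene lists and the 5 largest clonotypes per library. B cell genes were ranked without the candidate chain. The lists were IGHV5 with IGHV2, IGHV1, the B-1 type pairs, unswitched constant genes, IgG genes, IGKJ4 with IGKJ5, IGLV2 with IGLV3, the invariant NKT and MAIT alpha chains, and superantigen-reactive TRBV genes. The end of the candidate heavy chain, near copies of it, cells of at least 1000 UMIs, the doublet estimates and the thinning of heavy or light chains alone were defined after the data had been seen. The end was tried at lengths from 12 to 36 bases with 0 and 2 mismatches.

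Alternatives set the UMI minimum to 1 or 5, kept barcodes called in both tables, kept only cells with exactly 1 chain of each kind, thinned cells to 10 UMIs, allowed 2 mismatches to the candidates, and changed the definitions of second chain, clonotype and unit. The naming rule was tested on simulated profiles at the real cell numbers, with 3 genes doubled in each of 20 simulations. Doubled genes were drawn from those with at least 20 cells expected at the WT cell number, and no decrease was planted. The rule named 55.0% of doubled genes for IGHV (99 genes in the profile), 16.7% for IGKV (92), 68.3% for TRAV (90) and 95.0% for TRBV (22). Rescaling to whole profiles left the doubled genes at median changes of 1.91-fold, 1.94-fold, 1.91-fold and 1.72-fold. In profiles with no change it named 0.202%, 0.163%, 0.222% and 0.682% of genes. A planted candidate share of 40.2% was recovered as 40.2%. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.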

Results

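Single-cell V(D)J libraries of the B cell and T cell receptor were available from the spleen of 1 wild-type C57BL/6JRj mouse (WT) and 1 heterozygous 564Igi mouse. 564Igi is a line in which rearranged heavy (Igh) and kappa light (Igk) chain genes of an autoreactive antibody replace part of the germline loci. Splenocytes were depleted of Ter-119-positive erythroid cells before droplet capture. The B cell tables held 24740982 reads and 927382 unique molecular identifiers (UMIs) in WT and 20898886 reads and 747499 UMIs in 564Igi. The T cell tables held 30190690 reads and 86409 UMIs in WT and 32922893 reads and 114433 UMIs in 564Igi. After filtering, 6446 WT and 3798 564Igi B cells carried a productive chain, with medians of 56 and 35 UMIs per cell, and 3097 WT and 4347 564Igi T cells did, with medians of 15 and 14. A heavy chain was found in 74.6% of WT and 91.0% of 564Igi B cells with a light chain, so the heavy chain was recovered less often in WT. Each group was 1 mouse, so no difference below was tested against the spread between animals. Intervals are exact 95% binomial intervals, or Newcombe intervals for differences, and cover counting error only.

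The first comparison asked how much of the 564Igi B cell repertoire used the knocked-in chains. One heavy chain dominated the 564Igi B cells. It joined IGHV1-53 to IGHJ4 with the CDR3 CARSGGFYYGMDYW (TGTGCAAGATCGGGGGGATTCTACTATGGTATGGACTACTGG) and was the primary heavy chain of 1830 of 3471 cells, or 52.7% (51.0 to 54.4). One light chain was more widespread still. It joined IGKV4-59 to IGKJ5 with the CDR3 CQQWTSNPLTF (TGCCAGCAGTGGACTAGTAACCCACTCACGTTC) and was primary in 3288 of 3649 cells, or 90.1% (89.1 to 91.1). Both are called candidate chains here, because the labels do not give the knocked-in sequences. In GRCm38 the germline segments lie at chromosome 12, 115158445 to 115158835 (Ighv1-53), chromosome 12, 113428514 to 113428567 (Ighj4), chromosome 6, 69438218 to 69438741 (Igkv4-59), and chromosome 6, 70723886 to 70723923 (Igkj5). In WT the candidate heavy chain was primary in 0 of 4824 cells, which allows a share of up to 0.0622% (3 cells), and the candidate light chain in 0 of 6395, which allows up to 0.0469%. With up to 2 mismatches to the candidate and its V and J genes, the light chain was primary in 0.657% of WT cells.

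By primary chains, 49.9% (48.2 to 51.6) of 3322 paired 564Igi cells had both candidate chains and 40.5% (38.9 to 42.2) only the light chain. Only the heavy chain was primary in 1.38% (1.02 to 1.84), and neither in 8.16% (7.25 to 9.14). Cells with another primary chain could still hold a candidate as a second chain. Counted in any productive contig, the candidate light chain share was 94.8%. The candidate light chain accompanied 97.3% (96.4 to 98.0) of candidate heavy chains and 83.3% (81.3 to 85.0) of other heavy chains. As a background, the candidate heavy chain was also read in 19.4% (18.3 to 20.6) of 4573 564Igi barcodes called only as T cells, at a median of 3 UMIs, against a median of 19 UMIs in B cell barcodes. The candidate light chain was read in 2.67% (2.22 to 3.18) of those T cell barcodes, at a median of 1 UMI. The light chain share was 94.99% when cells were restricted to exactly 1 heavy and 1 light chain.

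**Figure D1:**
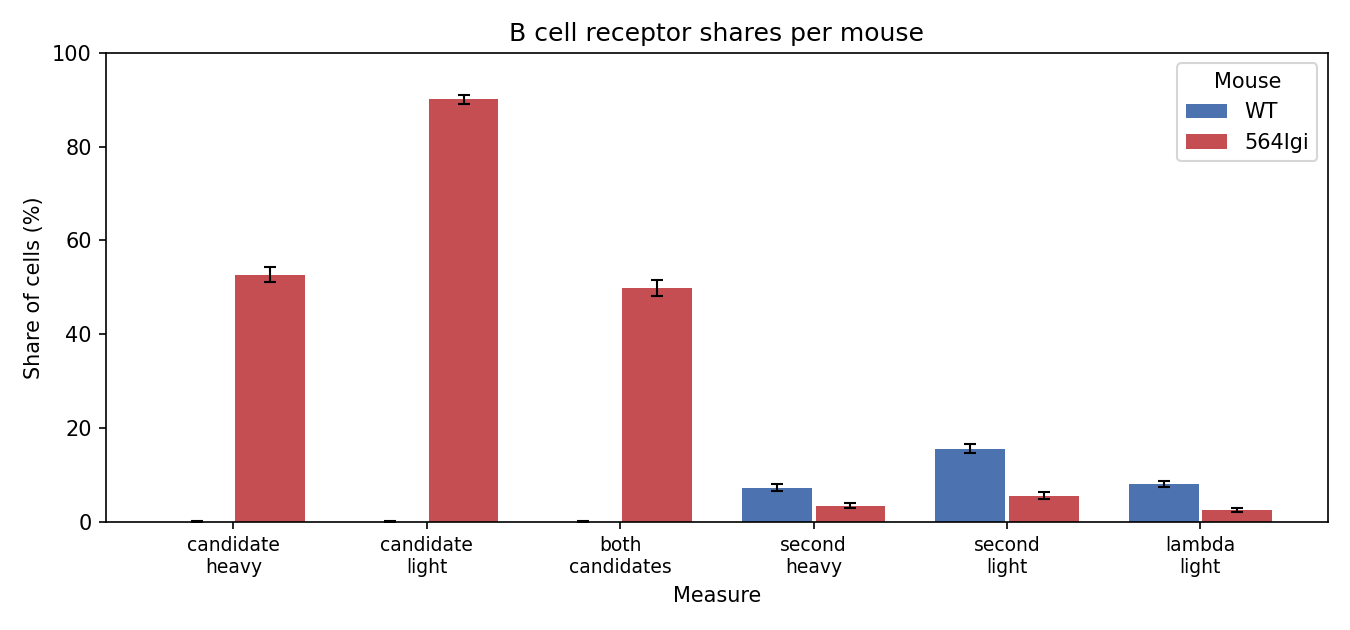
Share of B cells (%, y axis) with each receptor feature (x axis) in the WT and 564Igi mouse, with bars for the share and error bars for exact 95% binomial intervals. The candidate light chain reached 90.1% and the candidate heavy chain 52.7% in 564Igi, while second chains and lambda light chains were more frequent in WT.

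The second comparison concerned B cells that carry more than 1 receptor chain of a kind, or a lambda chain. All 3 shares were lower in 564Igi. A second productive light chain was present in 15.6% (14.7 to 16.5) of WT and 5.43% (4.71 to 6.21) of 564Igi cells, a difference of -10.2 points (-11.3 to -8.98). A second heavy chain was present in 7.26% (6.54 to 8.02) of WT and 3.40% (2.82 to 4.06) of 564Igi cells, a difference of -3.86 points (-4.82 to -2.88). Droplets with 2 B cells add second chains, and fewer visible ones in 564Igi, where most cells share a light chain. The barcodes called in both tables put such doublets at 5.29% of WT and 4.08% of 564Igi B cells. Taking off the second chains these would show left 10.3% and 4.66% for the light chain, a difference of -5.67 points (-6.97 to -4.35), and 1.97% and 0.456% for the heavy chain, a difference of -1.51 points (-2.62 to -0.375). Doublets estimated instead from cells with a second chain of both kinds left 6.35% and 4.28% for the light chain, a difference of -2.07 points (-3.23 to -0.898). Lambda light chains, made after kappa rearrangement in most B cells, were primary in 7.97% (7.32 to 8.67) of WT and 2.41% (1.94 to 2.96) of 564Igi cells. Within 564Igi the lambda share was 0.998% (0.582 to 1.59) with the candidate heavy chain and 3.96% (3.06 to 5.02) with another heavy chain. These shares count all light chains, and most 564Igi cells had the candidate, a kappa chain. Among paired cells with another primary light chain, 17 of 46 with the candidate heavy chain and 64 of 271 with another were lambda. In all, 88 564Igi cells had a lambda and 273 a non-candidate kappa chain, against 510 and 5885 in WT. The lower lambda share therefore does not hold among cells without the candidate light chain. IGLV2 and IGLV3 together made up 38.04% of WT and 27.3% of 564Igi lambda chains, a difference of -10.8 points whose interval (-20.7 to 0.589) included 0. IGLV1 made up 62.0% and 72.7%. The deposited high-confidence flag kept a further heavy chain only at 20% or more of the first one's UMIs, so weaker second heavy chains were not counted. After thinning every cell to 10 UMIs the heavy chain difference was -1.16 points (-1.98 to -0.322), but this also took more heavy chains from WT, where light chains had a median of 42 UMIs and heavy chains 14, against 18 and 18 in 564Igi. With the heavy chain UMIs alone thinned to 5 or 10 it was -3.97 (-4.92 to -3.02) and -5.56 points (-6.77 to -4.35), and with the light chain UMIs alone thinned to 5 or 10 the light chain difference was -9.24 (-10.3 to -8.14) and -9.60 points (-10.9 to -8.32).

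The third comparison asked whether B cells had switched isotype. Nearly all cells of both mice were unswitched. IGHM was the constant gene of 78.0% of WT and 81.8% of 564Igi heavy chains and IGHD of 21.4% and 17.2%, together 99.4% and 98.996%. Switched constant genes were found in 26 of 4527 WT cells, 0.574% (0.376 to 0.840), and in 34 of 3386 564Igi cells, 1.004% (0.696 to 1.40), a difference of 0.430 points (0.0230 to 0.873). Without chains that carry the end of the candidate heavy chain, described below, but with the candidate itself kept, the difference was 0.136 points. Of the non-candidate 564Igi chains without that end, 1.60% (0.879 to 2.68) were switched, still above the WT share. This group holds some near copies of the candidate (its length, 1 to 5 mismatches). Those numbered 29, and only 24 chains of that length carried the end. Their part in the 1.60% was not tested. IgG genes, the constant genes of the main serum antibody class, were higher in 564Igi, with 12 WT cells (0.265%, 0.137 to 0.463) and 31 564Igi cells (0.916%, 0.623 to 1.30), of which 10 carried a near copy of the candidate heavy chain (its length, 1 to 5 mismatches). IGHG2C was found in 2 WT and 11 564Igi cells, IGHG2B in 5 and 12, IGHG1 in 4 and 4, IGHG3 in 1 and 4, and IGHA in 14 and 3. The WT IGHA cells are not all separate clones. A WT clonotype of 4 cells was IGHA, and one of 7 cells was IGHA or had no named constant gene. In each, 1 cell held most UMIs (13370, then 19, and 12301, then 23). IGHE was found in 0 of 4527 and 0 of 3386 cells, which allows up to 0.0663% and 0.0886%. Within 564Igi, 0.278% (0.0902 to 0.647) of cells with the candidate heavy chain and 1.83% (1.23 to 2.62) of cells with another heavy chain were switched. The candidate was counted by exact match here. The other heavy chains therefore include its 29 near copies, of which 10 were switched, so part of this contrast comes from the matching rule.

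A further comparison covered the heavy chains of 564Igi cells other than the candidate. These used IGHJ4 in 60.0% (57.6 to 62.4) of 1641 cells, against 28.0% (26.7 to 29.3) of 4824 WT cells, while IGHJ1, IGHJ2 and IGHJ3 were lower, at 8.96%, 17.6% and 13.5% against 17.1%, 31.6% and 23.4%. Of the 1641 chains, 740, or 45.1% (42.7 to 47.5), ended in the last 30 bases of the candidate heavy CDR3 (GGGGGATTCTACTATGGTATGGACTACTGG) with up to 2 mismatches, and 0 of 4824 WT chains did, which allows up to 0.0622% (3 cells). These 740 cells carried 717 distinct CDR3 sequences and 76 V genes. Their CDR3 had a median of 20 amino acids, against 14 in the 901 other 564Igi cells and 14 in WT. Of the 740, 712 had a CDR3 longer than the candidate's and 24 had its length. The candidate's own V gene, IGHV1-53, was used by 44. Altered copies of the candidate can thus be among the chains with this end. This end was noticed in the data, and its length and mismatch limit were chosen after other settings had been tried. Exact matches over 30 bases numbered 700, while 24 bases with up to 2 mismatches matched 758 564Igi and 46 WT cells. Over 18 bases, up to 2 mismatches matched 918 564Igi and 976 WT cells, and exact matches numbered 740 and 2. The WT count of 0 thus depends on the setting. In the 901 cells without the end, IGHJ4 was used by 27.2% (24.3 to 30.2), and the IGHJ1, IGHJ2 and IGHJ3 differences from WT had intervals that included 0.

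**Figure D2:**
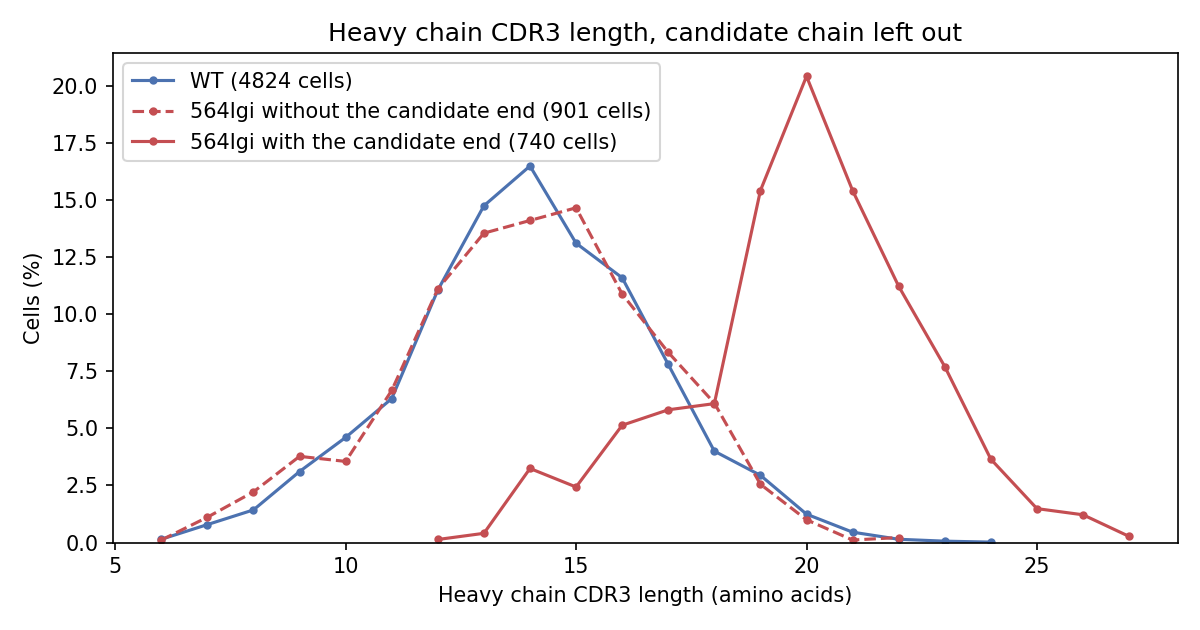
Distribution of heavy chain CDR3 length in amino acids (x axis) as a share of cells (%, y axis) for 4824 WT cells, 901 564Igi cells without the end of the candidate chain and 740 564Igi cells with it, the candidate chain itself left out. The 564Igi cells without the end had the WT median of 14 amino acids, and those with it a median of 20.

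V genes of the non-candidate heavy chains also differed between the mice. The distance between the 2 IGHV usage profiles was 25.8%, against 9.88% from counting noise alone. Higher in 564Igi were IGHV2-9, at 0.290% in WT and 2.74% in 564Igi, IGHV3-1, at 0.518% and 2.80%, IGHV1-53, at 2.45% and 4.14%, IGHV1-19, at 1.87% and 3.41%, and IGHV14-3, at 0.912% and 2.07%. IGHV1-53 is the candidate's own V gene, so altered copies of the candidate can add to its share. Lower in 564Igi were IGHV1-26, at 4.93% and 2.56%, IGHV1-82, at 2.90% and 0.914%, IGHV1-72, at 2.99% and 1.28%, IGHV1-76, at 1.97% and 0.670%, and IGHV1-50, at 1.91% and 0.609%. IGHV5 and IGHV2, families close to the D segments, made up 12.5% (11.6 to 13.5) of WT and 20.7% (18.8 to 22.8) of 564Igi chains, and the IGHV1 family 58.5% (57.1 to 59.9) and 47.1% (44.7 to 49.6). Without the chains that carried the candidate end, the distance was 16.5% against 12.4% from counting noise. The IGHV5 and IGHV2 share was then 16.2% (13.9 to 18.8), and the IGHV1 share 51.3% (48.0 to 54.6). Most of the gene differences were then smaller. Those of IGHV3-1, IGHV2-9 and IGHV1-53 went from 2.28, 2.45 and 1.70 points to 0.148, 0.487 and 0.218, those of IGHV1-26 and IGHV1-72 from -2.37 and -1.71 to -0.605 and -0.654, and that of IGHV1-19 changed sign, from 1.55 to -0.423. IGHV14-3 (1.31 points), IGHV1-82 (-1.57), IGHV1-76 (-1.08) and IGHV1-50 (-0.797) lay within the intervals of their full differences.

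**Figure D3:**
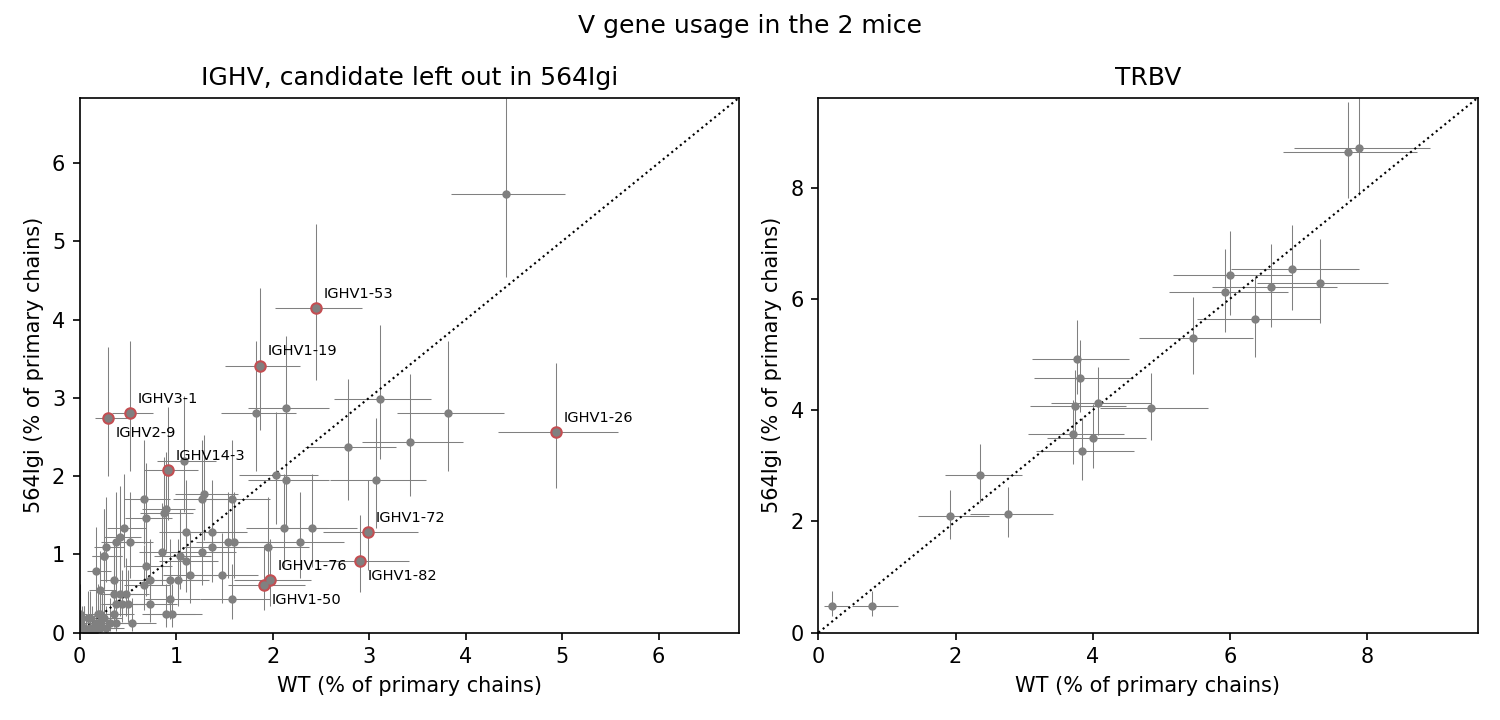
Usage of each IGHV gene (left, candidate left out in 564Igi) and each TRBV gene (right) as a share of primary chains (%) in WT (x axis) and 564Igi (y axis), with exact 95% intervals as error bars and the named genes, up to 5 per direction with intervals that do not overlap, labelled. IGHV2-9 and IGHV3-1 lie above the diagonal and IGHV1-26 below it, and no TRBV gene is labelled.

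Heavy CDR3 regions with a net charge of 1 or more, a feature studied in autoreactive antibodies, made up 24.2% (22.9 to 25.4) of WT and 33.0% (30.8 to 35.4) of non-candidate 564Igi chains. The share was 38.8% (35.3 to 42.4) in chains with the candidate end, and 28.3% (25.4 to 31.4) in those without it, 4.15 points (0.980 to 7.44) above WT.

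Kappa chains other than the candidate were primary in 273 564Igi cells. Some of these cells also held the candidate as a second light chain, since 3458 cells held it and it was primary in 3288. IGKJ4 or IGKJ5, the last J segments reached by repeated kappa rearrangement, were used by 38.8% (37.5 to 40.04) of 5885 WT cells and 50.9% (44.8 to 57.0) of these 273. IGKJ5 was higher, at 24.9% in WT and 39.2% in 564Igi, and IGKJ1 lower, at 30.7% and 17.2%, whereas IGKJ4 was used by 13.8% and 11.7%. IGKV4-59, the candidate's own V gene, was used by 1.68% and 11.7%, IGKV6-17 was used by 2.80% and 7.33% and IGKV6-23 by 2.33% and 5.13%. IGKV10-96 was used by 5.57% and 2.20%, and IGKV5-48 was used by 1.89% of WT cells and 0 of the 273, which allows up to 1.10%. With each distinct chain counted once, the differences were smaller for IGKV10-96 (-0.603 points, from -3.38), IGKJ1 (-7.28, from -13.5), IGKV6-17 (1.78, from 4.52) and IGKV6-23 (1.19, from 2.80). The IGKJ4 or IGKJ5 difference was 12.1 points (5.92 to 18.3). With near copies of the candidate light chain, of up to 2 mismatches, left out of both mice, it was 7.41 points, and IGKV4-59 was used by 0.976% (0.740 to 1.26) and 2.43% (0.897 to 5.21), a difference whose interval (-0.106 to 4.25 points) included 0. IGKJ5 was then used by 24.4% and 32.8%, a difference of 8.39 points (2.46 to 14.7). The IGKJ4 or IGKJ5 difference was 32.2 points, from 37.3% and 69.4%, in cells with exactly 1 heavy and 1 light chain. That setting leaves out cells with the candidate as a second light chain, keeps its near copies, and rests on fewer than the 273 cells.

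Clonal expansion was compared in cells without the candidate heavy chain, drawn to 1618 cells per mouse. Clonotypes of 2 or more cells held 0.563% of WT cells (0.124 to 0.989 over draws) and 3.71% of 564Igi cells, which were not drawn down. The difference of 3.15 points was 4.88 points (0.563% and 5.44%) with clonotypes defined by amino acid CDR3 and 2.69 points (0.348% and 3.04%) without members under 1% of the largest member's heavy chain UMIs. Without chains that carry the candidate end it was 2.44 points (0.365% and 2.80%). The largest WT clonotype had 7 cells (IGHV1-12, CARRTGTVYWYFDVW), but 1 of them held 12301 heavy chain UMIs and the next 23, and the third (IGHV9-3, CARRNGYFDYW, 4 cells) had 13370 and 19. Another 2 of the 5 largest WT clonotypes, of 4 and 3 cells, joined IGHV11-2 to IGKV14-126, the pair of B-1 cells that bind phosphatidylcholine, and the remaining one used IGHV2-9-1 in 3 cells. That pair was found in 13 of 4773 WT and 0 of 1618 564Igi cells, which allows up to 0.185%, and IGHV12-3 in 9 of 4824 and 1 of 1641. Of those 1618 cells, 1347 had the candidate light chain, with another V gene, as primary and could not show the pair. The remaining 271 are too few to tell a share like that of WT from none. In 564Igi the largest clonotypes used IGHV2-2 (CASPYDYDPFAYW, 4 cells), IGHV2-9 (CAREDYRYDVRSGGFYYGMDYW, 4 cells), IGHV1-26 (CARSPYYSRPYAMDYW, 3 cells), IGHV1-52 (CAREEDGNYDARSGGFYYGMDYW, 3 cells) and IGHV1-64 (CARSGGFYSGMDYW, 3 cells). All 5 paired with the candidate light chain, and the IGHV1-26 clonotype had 3632 UMIs in its first cell and 6 in its second. The IGHV2-9, IGHV1-52 and IGHV1-64 clonotypes carried the candidate end. The IGHV1-64 CDR3 differs from that of the candidate by 1 amino acid.

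The last comparison asked whether T cell receptors differed as well. Usage distances differed from counting noise by less than their own spread for all 4 segment types. They were 10.1% for TRAV, 7.12% for TRAJ, 5.62% for TRBV and 2.36% for TRBJ, against 9.10%, 6.65%, 4.18% and 3.01% from counting noise. With at least 5 UMIs per contig the TRAV and TRAJ distances moved to 14.7% and 9.40%, against 12.8% and 9.50% from counting noise in the fewer cells left. Only TRAV5-4 had intervals that did not overlap, at 3.03% (2.37 to 3.80) in WT and 1.79% (1.37 to 2.30) in 564Igi. TRBV genes reactive with endogenous mammary tumour virus superantigens (TRBV26, TRBV12-1, TRBV12-2 and TRBV16) made up 17.6% (16.2 to 19.01) and 18.2% (17.1 to 19.4). Chains named for both TRBV12-2 and TRBV13-2 are not in that sum, which was 25.3% and 26.9% with them. The list concerns superantigens presented by I-E, and I-E expression was not examined in either mouse. The shares therefore cannot tell whether these T cells were selected differently. The invariant NKT alpha chain, TRAV11 or TRAV11D with TRAJ18, was found in 31 of 2346 WT (1.32%, 0.900 to 1.87) and 61 of 3343 564Igi cells (1.82%, 1.40 to 2.34), a difference of 0.503 points (-0.192 to 1.17) that was not detectable at this depth. The MAIT-type alpha chain was found in 0 of 2346, which allows up to 0.128%, and 2 of 3343 cells. A second alpha chain was present in 14.2% (12.8 to 15.7) and 14.6% (13.4 to 15.8), and a second beta chain in 4.82% (4.08 to 5.65) and 6.91% (6.16 to 7.73). Doublets of 2 T cells, estimated from the barcodes called in both tables, made up 2.65% and 4.87% of T cells, a gap similar to that in second beta chains. Clonotypes of 2 or more cells held 1.80% of WT and 0.855% (0.496 to 1.17 over draws) of 564Igi T cells at 2217 cells per mouse, a difference of -0.949 points that was -0.484 (1.21% and 0.724%) with at least 5 UMIs per contig.

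The largest T cell clonotypes were small. In WT they used TRBV17 (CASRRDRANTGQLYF, 7 cells), TRBV12-2 (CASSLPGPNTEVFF, 4 cells), TRBV19 (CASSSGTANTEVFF, 4 cells), TRBV12-1 (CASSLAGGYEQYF, 3 cells) and TRBV12-2 (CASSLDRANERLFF, 2 cells). In 564Igi they used TRBV19 (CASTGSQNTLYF, 6 cells), TRBV5 (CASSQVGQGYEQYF, 4 cells), TRBV20 (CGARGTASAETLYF, 3 cells), TRBV12-1 (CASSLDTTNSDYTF, 2 cells) and a chain named for both TRBV12-2 and TRBV13-2 (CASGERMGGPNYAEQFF, 2 cells). Among barcodes called in 1 table only, B cells made up 66.6% (65.7 to 67.6) of 9776 in WT and 45.6% (44.5 to 46.6) of 8400 in 564Igi. Recovery of the B and T cell libraries also sets this share.

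**Figure D4:**
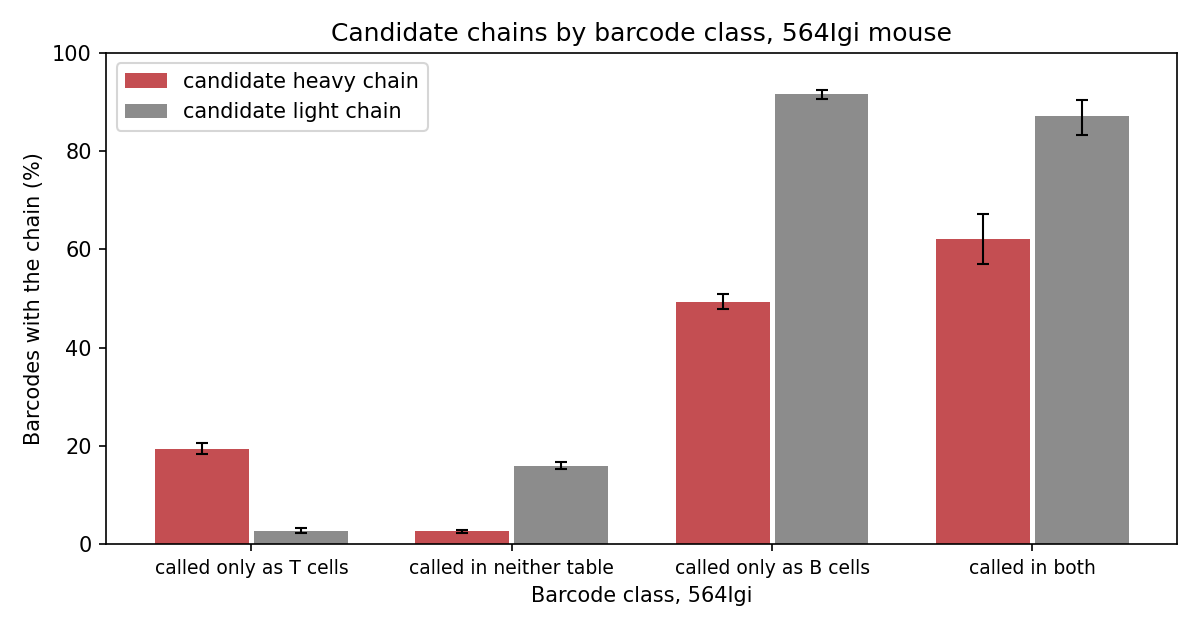
Share of 564Igi barcodes (%, y axis) in which any contig held the candidate heavy or light chain, by barcode class (x axis), with exact 95% binomial intervals as error bars. Barcodes called only as T cells held the heavy chain in 19.4% and the light chain in 2.67%, and barcodes called in neither table held them in 2.59% and 15.99%.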

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

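All tests of an explanation in this part were chosen only after the result was seen. Barcodes called only as T cells or in neither table are not used for B cell receptors in the comparisons between the mice, and the values from called B cells are given for reference.

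The candidate heavy chain appeared in 19.4% of 4573 564Igi barcodes called only as T cells, against 1 of 3263 in WT. Free RNA and B cells sharing the droplet would bring both candidate chains in the ratio of their source. The heavy chain instead made up 94.2% of both chains' UMIs there, against 22.0% in barcodes called in neither table and 21.0% in B cell barcodes. These are pooled UMIs, with up to 4150 heavy chain UMIs in 1 B cell barcode, so no interval is given. Counted by barcodes that held each chain, the heavy chain made up 87.9%, 13.9% and 35.0% of detections. These values argue against free RNA as the main cause. They cannot decide on shared droplets. T cell barcodes also called as B cells, where the UMI share was 11.7%, are left out of this class. A constant gene, IGHM or IGHD, was named in 72.5% (69.5 to 75.4) of these 888 barcodes, IGHM in 639 and IGHD in 5. In barcodes called in neither table IGHM was named in 145 and IGHD in 28 of 311. In B cell barcodes they were named in 1443 and 403 of 1890. Free or B cell RNA also carries a constant gene, so its presence does not separate the explanations. A candidate explanation, as a hypothesis, is low transcription of the knocked-in heavy chain gene in T cells, which the expression libraries, not analysed here, would be needed to test.

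Single chains were spread over barcodes called in neither table. The WT kappa chain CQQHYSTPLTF was read in 9.07% of 10780 such barcodes, against 5 of 12010 in 564Igi, and reached 11099 UMIs in 1 called WT cell. In 564Igi the candidate light chain was read as a productive contig in 15.6% of 12010 such barcodes and the candidate heavy chain in 1.87%, against 0 of 10780 in WT, which allows up to 0.0278%. The heavy chain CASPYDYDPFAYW, that of a 564Igi clonotype of the largest size (4 cells), was read in 1.03%.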

How the results depend on the processing

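Alternatives that leave out chains with the candidate end, near copies of the candidate light chain or low-UMI clonotype members, that thin heavy or light chains alone, or that keep contigs without the high-confidence flag, were chosen only after the result was seen. No paired analysis was possible because each group was 1 mouse and no result comes from a test. Of 100 alternative values of the compared results, 88 lay within the counting interval of the main value, 12 lay outside it and 0 reversed. Of 162 values of named genes, other loci and subgroups, 141 lay within it, 17 outside it and 4 reversed. Of 93 alternative values of share differences, 91 kept their direction, and the other 2 were second alpha chain differences, whose main interval included 0. The rule of 20% of the first chain's UMIs changed no second heavy, alpha or beta chain value, since the deposited flag had already removed those chains, so it says nothing about their stability. Without the flag the second heavy chain difference was -4.05 points and the second light chain difference -11.3 points.

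Restricting to cells with exactly 1 chain of each kind moved the candidate heavy chain share to 54.5%, the light chain share to 94.99%, both to 53.5%, the lambda difference to -6.79 points and the IGKJ4 or IGKJ5 difference to 32.2 points. The cause was not tested. Counting any productive contig moved the candidate light chain share to 94.8%, by construction. Thinning to 10 UMIs moved the second heavy chain difference to -1.16 points and thinning heavy chains alone to 10 UMIs moved it to -5.56 points, amino acid clonotypes moved the B cell expansion difference from 3.15 to 4.88 points, and requiring a paired receptor moved the B cell share difference from -21.1 to -17.0 points. The cause was not tested. Leaving out chains with the candidate end moved the net charge difference to 4.15 points and the IGHV distance to 16.5%. It reversed the differences of IGHJ2 (0.393 points), IGHJ3 (1.15) and IGHJ4 (-0.793), because the chains left out all used IGHJ4, and that of IGHV1-19 (-0.423), of whose 56 chains 43 carried the end. It moved IGHV3-1 to 0.148 points, IGHV2-9 to 0.487, IGHV1-53 to 0.218, IGHV1-26 to -0.605, IGHV1-72 to -0.654 and IGHJ1 to -0.745. Counting each distinct chain once moved IGKV10-96 to -0.603 points, IGKJ1 to -7.28 and the IGLV distance from 10.8% to 23.3%. Leaving near copies of the candidate light chain out of both mice moved IGKV4-59 to 1.45 points. A minimum of 5 UMIs moved the TRAV distance to 14.7% and the TRAJ distance to 9.40%, with counting noise of 12.8% and 9.50% there. The switched difference ranged from 0.136 to 0.591 points. It was lowest without chains that carry the candidate end, a setting that kept the candidate itself. The 564Igi kappa results rest on 273 cells, on fewer in cells with exactly 1 chain of each kind, and the IGLV results on 88.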

Other observations

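All tests in this part were chosen only after the result was seen.

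Isotype also differed within the 564Igi heavy chains close to the candidate. Chains of the candidate's length with 1 to 5 mismatches were found in 29 cells, and 10 of them, 34.5% (17.9 to 54.3), were switched, with IGHG2C in 5, IGHG2B in 4 and IGHG3 in 1. Switched chains made up 2.11% (1.18 to 3.45) of all chains with the candidate end and 1.60% (0.879 to 2.68) of those without it. Some of the 29 near copies lack the end and are counted among the latter. Cells with at least 1000 receptor UMIs numbered 30 of 6446 in WT and 45 of 3798 in 564Igi. In 564Igi 9 of the 44 with a heavy chain, 20.5% (9.80 to 35.3), had the candidate as primary heavy chain, against 53.1% (51.4 to 54.8) of other cells. Their candidate light chain share was 61.4% (45.5 to 75.6), against 90.8% (89.8 to 91.8). In WT 7 of the 30 were switched, against 4 of 44 in 564Igi. The V genes joined to the candidate end differed in profile from WT, at a distance of 45.4% against 13.6% from counting noise. IGHV3-1 made up 5.41% (3.89 to 7.29) and IGHV2-9 5.14% (3.66 to 6.98) of chains with the end, against 0.666% and 0.777% of 564Igi chains without it. These are large contrasts, whereas IGHV9-3, the most frequent gene with the end, made up 6.08% and 5.22%. Distinct beta chains shared between the mice numbered 9, and distinct alpha chains 48.

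The 564Igi heavy chains with the candidate end were weighed first. Chance rearrangement is argued against by WT, where the share with the end had an exact 95% upper bound of 0.0764%. Chimeric molecules are argued against because 0 of these 740 cells, or 0% (up to 0.405%), held a heavy contig of the same V gene without the end. In 1 cell a contig of that V gene had no CDR3 to read. Altered copies of the candidate's own length can be at most 24 of the 740, and 712 had a longer CDR3. Joining of upstream segments to the knocked-in heavy chain gene cannot be told apart from other causes that remain. Distinct CDR3 sequences numbered 96.9% of cells, but WT heavy chains were nearly all distinct too (99.0%), so this decides nothing, and the joining sequence was not tested.

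The lower second chain shares in 564Igi were weighed next. Depth is argued against for the light chain by a difference of -9.24 points with light chains thinned to 5 UMIs, within the full interval, and the free WT chain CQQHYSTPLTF by -9.91 points without it. For the heavy chain, depth is argued against by a difference of -3.97 points with heavy chains thinned to 5 UMIs, within the full interval, and by the lower median of 14 heavy chain UMIs in WT against 18 in 564Igi. Doublets cannot be told apart from other causes for either chain. Doublets of 564Igi cells that share a candidate chain show no second chain. In WT 80.8% (76.3 to 84.8) of cells with a second heavy chain and any light chain also held a second light chain, as doublets would, and doublets estimated from barcodes called in both tables left a heavy chain difference of -1.51 points. For the light chain they left -5.67 points. An estimate from second heavy chains in cells with a second light chain, 33.9% in WT against 57.2% if all were doublets with the heavy chain recovery of other cells, left -2.07 points (-3.23 to -0.898). Both estimates rest on assumed pairing or recovery. A difference in allelic exclusion between the genotypes stays open as untested.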
